A study of Solanum tuberosum with 12 samples.

How the data were processed

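RNA was measured in 12 libraries of potato shoot tips, 3 biological replicates in each of 4 groups: non-cryopreserved under cool white fluorescent light, and cryopreserved with recovery under cool white light, under red and blue LEDs, or in darkness. Per the labels' protocols, each sample pooled 10 shoot tips, RNA with an integrity number above 7.4 was used, and stranded libraries were made from polyadenylated RNA with a TruSeq kit. The deposited files hold raw read counts per gene, 1 file per sample, with no normalization by the authors. The submitters' processing notes name FastQC 1.11.2, TopHat2 2.0.8b, Bowtie 1.1.1, featureCounts 1.5.0 and DESeq2 1.14.1. The genome build, the annotation release, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here, so counts of overlapping, antisense or near-identical genes are uncertain. No row without a gene identifier was found.

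The count tables list 39027 genes under identifiers that start with PGSC0003DMG. These were looked up in a RefSeq gene table of the assembly SolTub_3.0 with 32873 genes, and 0 identifiers matched. The files do not pair identifiers with names, so genes are given by identifier, and 52 gene lists and sets of cell type markers that had been fixed beforehand had no matched member and were not tested. No coordinates are given.

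Totals per library ranged from 6342324 to 10572258 counts, and 11589 genes had 0 counts in every library. Groups and replicate numbers were taken from the labels. Replicate pairs of a group differed by more than counting noise, with a chi-square per degree of freedom between 3.02 and 20.5, so no library was counted as a repeat of another. A gene with no read in a group was given a floor of 3 reads over the group, which is 0.137 CPM in non-cryopreserved tips and 0.124, 0.111 and 0.139 CPM in cryopreserved tips under cool white light, under LEDs and in darkness. Such floors cover counting error only.

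Differential expression was tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 19920 genes. Counts were scaled by TMM factors, and the quasi-likelihood functions glmQLFit and glmQLFTest were fitted to all 12 libraries with group as the factor, leaving 8 residual degrees of freedom. The common biological coefficient of variation was 13.2%. The 6 pairs of groups were contrasted with two-sided tests, and a further test asked for any difference among the 3 recovery conditions. The p-values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison, and genes with an adjusted p under 0.05 were called. Values printed per gene are TMM-normalized CPM with the SD over 3 libraries, and log2 fold changes with their standard errors. Each standard error was computed back from the test, as the absolute log2 fold change over the square root of the quasi-likelihood F statistic. The design, the rule for naming genes and the alternatives were fixed before the data were examined, except where stated. The rule took called genes with a mean log2 CPM of at least 1 whose libraries did not overlap between the 2 groups. With no gene names, its fallback of the 2 largest increases and the 2 largest decreases per comparison was used, which gave 16 identifiers.

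Overlaps of calls between comparisons that share libraries were set beside the overlap of independent lists, and correlations of their fold changes beside 20 simulations of unchanged groups. The tests were run on simulated counts for the 19920 genes, of which 200 were changed, 100 of them by 2-fold and 100 by 4-fold. For cool white against non-cryopreserved tips, 62% of the 2-fold and 93% of the 4-fold changes were recovered, and 7.19% of calls were false. For LEDs against non-cryopreserved tips the values were 66%, 94% and 6.98%, and for darkness against non-cryopreserved tips 67%, 86% and 3.16%. For LEDs against cool white light they were 63%, 90% and 6.71%, for darkness against cool white light 64%, 88% and 5%, and for LEDs against darkness 69%, 92% and 6.94%. The test of any light difference recovered 67% and 91%, with 4.24% false calls. Except between LEDs and cool white light, the real comparisons called far more than 200 genes, so these rates need not hold for them. The rates need not hold between LEDs and cool white light either. There the chi-square per degree of freedom between replicates reached 20.5 under LEDs, against 5.65 under cool white light, and the real count rested on few libraries.

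Alternatives were scaling by DESeq2 size factors, by upper quartiles or by library size only, DESeq2 1.42.0 and limma 3.58.1 voom in place of edgeR, no filter and a filter of at least 1 CPM in 3 libraries, fits of only the groups compared, replicate number as a block, each library left out in turn, and a minimum change of 2-fold. Thinning each library to the smallest total of 6342324 counts was added after the data had been seen, as were the sets of genes called in several light comparisons and the counts of genes with opposite responses. Figures were drawn with matplotlib 3.10.9.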

Results

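Potato (Solanum tuberosum) shoot tips of the genotype Agrie Dzeltenie, cut from plants grown in vitro, were profiled by RNA sequencing in 12 libraries that fall into 4 groups of 3 biological replicates. Shoot tips of 1 group were not cryopreserved and were kept under cool white fluorescent light. The other groups had been cryopreserved in droplets of 10% dimethyl sulfoxide (DMSO), a cryoprotectant that enters cells and limits ice formation, and held in liquid nitrogen for 1 h. They were rewarmed, kept on regeneration medium in darkness for 48 h, and then placed for 16 h under cool white light, under light-emitting diodes (LEDs) giving 90% red and 10% blue light, or in continued darkness. Light was given at 40 µmol per square metre per second, and 10 shoot tips were pooled for each library. The comparisons ask how gene expression in recovering shoot tips differs from that in tips that were never frozen, and how far the light given during early recovery changes it. The labels do not say whether the non-cryopreserved tips also spent 48 h in darkness or on regeneration medium, so differences from that group cover cryopreservation together with any such difference in handling.

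Each library held between 6342324 and 10572258 counted reads. Of the 39027 genes in the count tables, 27438 had a read in at least 1 library and 19920 had enough reads to be tested. The files do not pair these gene identifiers with names, so genes are given by identifier and are grouped by how they responded. At an equal depth of 6342324 reads, a mean of 23971 genes (SD 82.9, n = 3) was detected in cryopreserved tips under cool white light, 23701 (SD 93.5, n = 3) under LEDs, 23358 (SD 69.7, n = 3) in darkness and 23427 (SD 149, n = 3) in non-cryopreserved tips. The cool white group lay above the dark group in every library, with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries can give. The 10 most abundant genes of a library took 5.02% of its reads (SD 0.0810, n = 3) under cool white light, 5.98% (SD 0.469, n = 3) in non-cryopreserved tips, 6.48% (SD 0.211, n = 3) under LEDs and 7.09% (SD 1.21, n = 3) in darkness.

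The first principal component of the tested genes held 56.1% of the variance and separated the non-cryopreserved libraries from all 9 cryopreserved libraries. The second held 16.8% and separated the dark libraries from those of both lights. Correlations of log2 expression between libraries, taken across genes, ranged from 0.975 to 0.982 within the non-cryopreserved group, from 0.982 to 0.986 under cool white light and from 0.979 to 0.983 in darkness. Under LEDs they ranged from 0.964 to 0.976, and LED libraries correlated about as well with cool white libraries (0.965 to 0.976) as with each other.

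**Figure D1:**
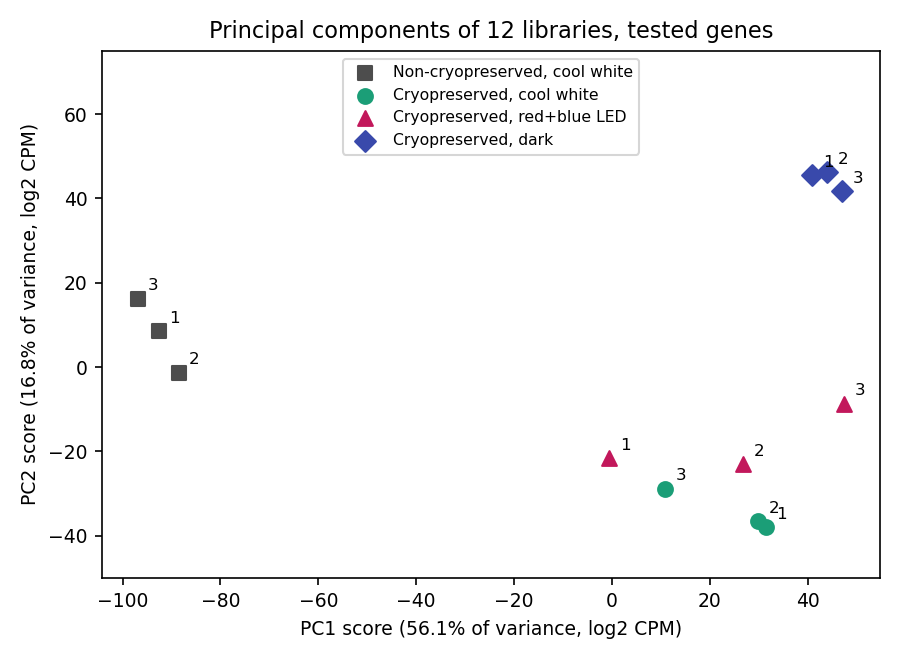
Scores of the 12 libraries on the first principal component (x axis, 56.1% of the variance of log2 CPM, the read count scaled to library size) and on the second (y axis, 16.8%), with the replicate number beside each point. Non-cryopreserved libraries lie on the left, the 3 dark libraries lie at the upper right, and the 3 LED libraries are spread more widely than those of any other group.

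In cryopreserved tips under cool white light, 5534 genes were higher and 4289 lower than in non-cryopreserved tips, together 49.3% of the genes tested. Large differences were mostly increases, since 2580 of the called genes were at least 2-fold higher and 1219 at least 2-fold lower, and 94 were at least 16-fold higher against 24 at least 16-fold lower. PGSC0003DMG400005030 had no read in any non-cryopreserved library and reached 11.5 ± 3.86 CPM (SD, n = 3; CPM is the read count scaled to library size and TMM-normalized) after cryopreservation, at least 83.9-fold higher than the level that 3 reads over the non-cryopreserved group would give (0.137 CPM). PGSC0003DMG400024597 was likewise at 0 without cryopreservation and at 9.82 ± 5.21 CPM (SD, n = 3) after it, at least 71.7-fold higher. PGSC0003DMG400034808 fell from 101.2 ± 10.1 to 1.74 ± 1.13 CPM (SD, n = 3), and PGSC0003DMG400004953 from 25.4 ± 5.94 to 1.06 ± 0.509 CPM (SD, n = 3).

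In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, PGSC0003DMG400034808 differed by a log2 fold change of -5.82 (SE 0.25) with an adjusted p of 1.26e-08, and PGSC0003DMG400004953 by -4.55 (SE 0.48) with an adjusted p of 5.51e-06. Without cool white replicate 3 the log2 fold change of PGSC0003DMG400034808 was -6.52. The same test gave adjusted p of 0.00694 for PGSC0003DMG400005030 and 0.00267 for PGSC0003DMG400024597. Among all tested genes, 59.9% had cool white and non-cryopreserved libraries that did not overlap, where chance gives 10%. Here and below, this 10% is an average over splits of the libraries compared. Genes are not independent, and the spread of that share between splits is not known here. The balance of higher and lower genes turned with the scaling, with 4783 higher and 5174 lower under upper quartile normalization and 5994 higher and 3784 lower with library size only.

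Under LEDs, 5436 genes were higher and 4650 lower than in non-cryopreserved tips. The same 2 identifiers that were silent without cryopreservation led the increases. PGSC0003DMG400024597 was at 14.8 ± 15.9 CPM (SD, n = 3), at least 108-fold above the non-cryopreserved group, and PGSC0003DMG400005030 at 12.5 ± 16.8 CPM (SD, n = 3), at least 91.1-fold above it. Replicate 3 carried most of these reads, with 318 of the 406 of PGSC0003DMG400024597 and 309 of the 355 of PGSC0003DMG400005030, and without it the bounds were 41.9-fold and 20.2-fold. PGSC0003DMG400034808 fell to 0.946 ± 0.343 CPM (SD, n = 3), and PGSC0003DMG403017980 fell from 48.2 ± 4.58 to 0.980 ± 0.596 CPM (SD, n = 3), or to 0.639 CPM without LED replicate 2.

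By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, PGSC0003DMG400034808 differed from the non-cryopreserved tips by a log2 fold change of -6.70 (SE 0.27) with an adjusted p of 5.21e-09, and PGSC0003DMG403017980 by -5.72 (SE 0.30) with an adjusted p of 6.10e-08. The adjusted p from the same edgeR test was 0.00108 for PGSC0003DMG400024597 and 0.00552 for PGSC0003DMG400005030. With limma voom the call of PGSC0003DMG400005030 was lost at an adjusted p of 0.0587, the highest of its alternatives, which reached down to 6.85e-07. LED and non-cryopreserved libraries did not overlap for 56.2% of tested genes, against 10% by chance. Upper quartile normalization turned the balance to 4778 higher and 5277 lower genes.

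In continued darkness, 5508 genes were higher and 5488 lower than in non-cryopreserved tips. Strong decreases were more frequent than under either light, with 2245 called genes at least 2-fold lower, against 1219 under cool white light and 1366 under LEDs, and 93 at least 16-fold lower, against 24 and 27. PGSC0003DMG400033688 fell from 51.0 ± 2.13 to 0.221 ± 0.198 CPM (SD, n = 3), while it stood at 11.4 ± 2.22 CPM (SD, n = 3) under cool white light and 5.37 ± 5.01 CPM (SD, n = 3) under LEDs. LED replicate 1 held 120 of its 159 reads under LEDs, and without that library the LED mean was 2.49 CPM. PGSC0003DMG400029620 had no read in any dark library and 3.56 ± 0.945 CPM (SD, n = 3) in non-cryopreserved tips, at least 25.5-fold lower in darkness. PGSC0003DMG400005030 at 13.0 ± 9.91 CPM (SD, n = 3) and PGSC0003DMG400024597 at 10.5 ± 5.87 CPM (SD, n = 3) again led the increases, at least 95.2-fold and 76.3-fold, or 61.9-fold for PGSC0003DMG400005030 without dark replicate 3.

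With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, PGSC0003DMG400033688 differed by a log2 fold change of -7.69 (SE 0.66) with an adjusted p of 7.75e-07, and by -8.32 without dark replicate 2. The same edgeR test gave adjusted p of 0.000137 for PGSC0003DMG400029620, 0.00485 for PGSC0003DMG400005030 and 0.00208 for PGSC0003DMG400024597. Dark and non-cryopreserved libraries did not overlap for 61.8% of tested genes, where chance gives 10%. The even balance of higher and lower genes did not hold under upper quartile normalization, with 4926 higher and 6120 lower.

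**Figure D2:**
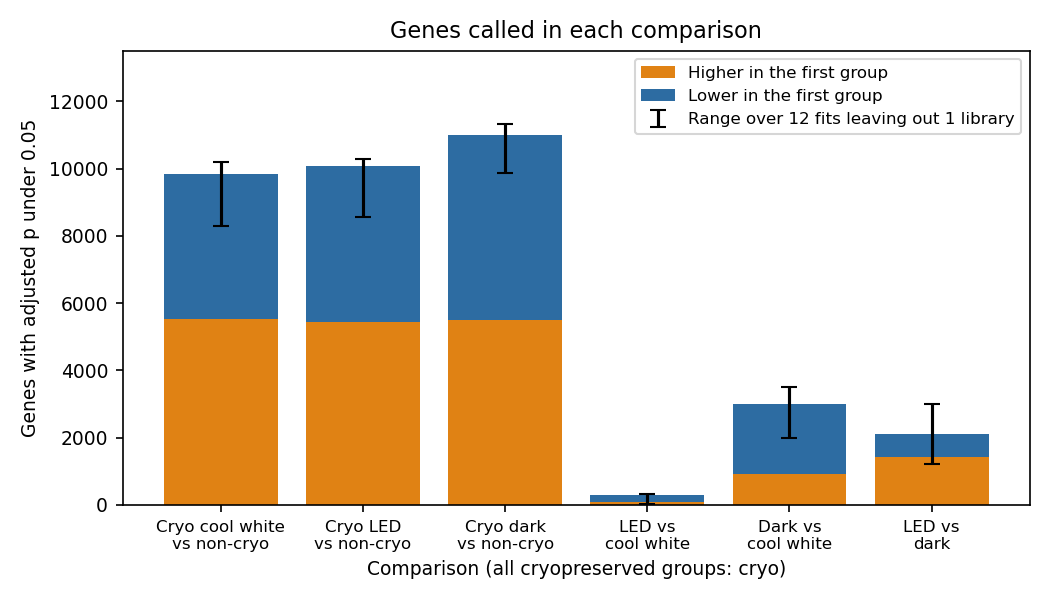
Number of genes with an adjusted p under 0.05 in each of the 6 comparisons (y axis), split into genes higher and lower in the first group named, with error bars from the lowest to the highest count when each of the 12 libraries was left out in turn. The 3 comparisons with non-cryopreserved tips called 9823, 10086 and 10996 genes, and the comparisons between lights 287, 2986 and 2118.

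A large set of genes responded in the same direction in all 3 recovery conditions. Of the 13655 genes called against non-cryopreserved tips in at least 1 condition, 3980 were higher and 3126 lower in all 3 conditions, a balance that upper quartile normalization turned to 3425 higher and 3729 lower. At least 2-fold changes in every condition were found for 1689 of the higher and 674 of the lower genes. Independent lists of these sizes would share 418 higher and 276 lower genes. Fold changes correlated across genes at r = 0.927 between cool white and LED, 0.818 between cool white and dark, and 0.859 between LED and dark, where unchanged groups simulated against the same control libraries gave 0.512, 0.503 and 0.508. The covariances were 0.883, 0.906 and 0.950 against simulated values of 0.0378, 0.0379 and 0.0379. The 3 control libraries are too few to be split, so part of the shared calls may come from the shared controls, and genes are not independent replicates. Among the 7106 shared genes, 1067 were also called in a comparison between lights.

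Between darkness and cool white light after cryopreservation, the differences were mainly lower expression in the dark. There were 2079 genes lower and 907 higher in darkness, and of those differing at least 2-fold 1113 were lower and 108 higher. PGSC0003DMG400017556 stood at 145 ± 13.7 CPM (SD, n = 3) under cool white light and at 0.879 ± 0.107 CPM (SD, n = 3) in darkness, with 108 ± 31.0 CPM (SD, n = 3) under LEDs and 122 ± 29.0 CPM (SD, n = 3) in non-cryopreserved tips. PGSC0003DMG400029620 was at 7.03 ± 3.87 CPM (SD, n = 3) under cool white light and had no read in darkness, at least 50.4-fold lower. PGSC0003DMG400020931 rose from 1.01 ± 0.807 CPM under cool white light to 6.49 ± 1.63 CPM in darkness (SD, n = 3), and PGSC0003DMG400002825 from 1.13 ± 0.693 to 5.52 ± 0.932 CPM (SD, n = 3).

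For these genes edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave a log2 fold change of -7.33 (SE 0.33, adjusted p 1.22e-08) for PGSC0003DMG400017556, 2.69 (SE 0.52, adjusted p 0.00281) for PGSC0003DMG400020931 and 2.28 (SE 0.49, adjusted p 0.00543) for PGSC0003DMG400002825. The log2 fold change of PGSC0003DMG400020931 was 3.52 without cool white replicate 2, and that of PGSC0003DMG400002825 was 2.89 without cool white replicate 1. The adjusted p of PGSC0003DMG400029620 in the same edgeR test was 0.000106. Dark and cool white libraries did not overlap for 36.9% of tested genes, against 10% by chance. The excess of lower over higher genes depended on the scaling in size, with 472 higher and 2503 lower when only library size was used and 1259 higher and 1940 lower with DESeq2 size factors. The 907 higher genes became 461 and 426 without cool white replicate 1 or 2, and 478 without dark replicate 1.

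Between LED light and darkness, 1429 genes were higher and 689 lower under LEDs, and at least 2-fold differences were found for 731 higher and 138 lower genes. Both leading increases were in genes that also led the comparison of cool white light with darkness. PGSC0003DMG400017556 was higher under LEDs by a log2 fold change of 6.90 (SE 0.33), with an adjusted p of 4.08e-08 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. PGSC0003DMG400029620, with no read in darkness, was at 3.30 ± 1.55 CPM (SD, n = 3) under LEDs, at least 23.7-fold higher, with an adjusted p of 0.00139 in the same edgeR test. PGSC0003DMG400005051 was at 0.967 ± 0.907 CPM under LEDs and 7.22 ± 5.13 CPM in darkness (SD, n = 3), and PGSC0003DMG400004875 at 0.662 ± 0.144 and 4.01 ± 1.34 CPM (SD, n = 3). For PGSC0003DMG400005051, LED replicate 3 held 19 of the 26 reads under LEDs and dark replicate 3 held 84 of the 149 in darkness.

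Their log2 fold changes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were -2.87 (SE 0.61, adjusted p 0.00850) for PGSC0003DMG400005051 and -2.56 (SE 0.41, adjusted p 0.00127) for PGSC0003DMG400004875. The log2 fold change of PGSC0003DMG400005051 was -4.07 without LED replicate 3 and -2.17 without dark replicate 3. LED and dark libraries did not overlap for 27.2% of tested genes, against 10% by chance. The count of 2118 called genes fell to 1264 when only the 6 libraries compared were fitted, to 1211 without LED replicate 2, to 1318 without dark replicate 1 and to 1295 without dark replicate 3. In the same order, the 1429 higher genes became 928, 878, 937 and 960, and the 689 lower genes 336, 333, 381 and 335, or 1068 without LED replicate 3. Library size scaling alone gave 1789 higher and 477 lower genes.

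Genes that differed from darkness under both lights form a light-responsive set of 1133 genes that were higher and 284 that were lower in light. The 1133 genes had a median log2 difference from darkness of 1.33 under cool white light and 1.07 under LEDs. Relative to non-cryopreserved tips their median was -1.29 in darkness, 0.05 under cool white light and -0.23 under LEDs. In darkness 957 of them were lower than in non-cryopreserved tips and 28 higher, whereas under cool white light 698 did not pass the test against that group, 270 were higher and 165 lower. Of the 284 genes lower in light, 196 were higher and 33 lower in darkness than in non-cryopreserved tips, with a median of 0.78 in darkness, 0.15 under cool white light and 0.17 under LEDs. Under cool white light 112 of the 284 were higher and 72 lower than in non-cryopreserved tips, and 100 did not pass the test.

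Independent lists of called genes would share 149 higher and 31.4 lower genes. Fold changes of the 2 lights against darkness correlated across genes at r = 0.823 against 0.515 for simulated unchanged groups, with a covariance of 0.313 against 0.0382. These comparisons share the 3 dark libraries, and the set was chosen on those libraries and on the libraries of both lights. Low dark and high light values in the 1133 genes are in part a product of that choice. So are high dark and low light values in the 284. The medians and counts under light against non-cryopreserved tips are shaped by that choice as well. Independent lists would place 312 of the 1133 genes among those lower and 313 among those higher in darkness than in non-cryopreserved tips, and 78.2 and 78.5 of the 284. Under cool white light they would place 315 of the 1133 genes among those higher and 244 among those lower, and 78.9 and 61.1 of the 284. Over all genes, the fold changes of cool white light and of non-cryopreserved tips against darkness correlated at r = 0.513, against 0.506 for simulated unchanged groups, with the same sign in 62.1% of genes against 66.9% and a covariance of 0.380 against 0.0382. The set of 284 fell to 165 with library size scaling, to 159 and 150 without cool white replicate 1 or 2, to 150 without LED replicate 2, and to 149, 180 and 155 without dark replicate 1, 2 or 3.

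**Figure D3:**
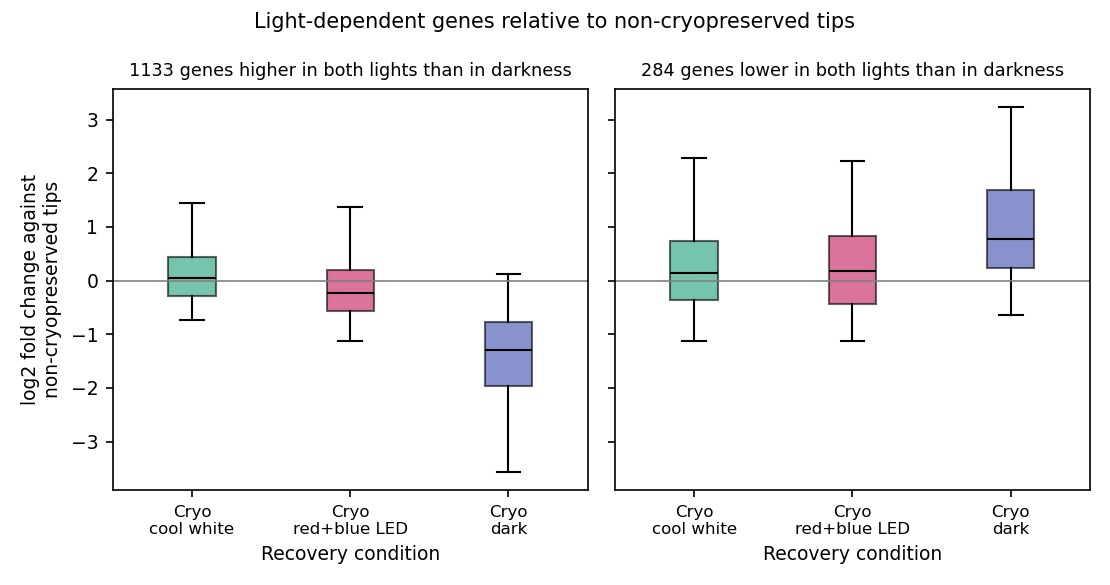
Log2 fold change against non-cryopreserved tips (y axis) under each recovery condition (x axis) for the 1133 genes higher in both lights than in darkness (left) and the 284 genes lower in both lights (right). Lines within boxes are medians, boxes span the quartiles, and whiskers reach the 5th and 95th percentiles over genes. The median of the 1133 genes is -1.29 in darkness and 0.05 under cool white light.

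Few genes were called between LED and cool white light, with 75 higher and 212 lower under LEDs among the 287. PGSC0003DMG400013010 was at 41.3 ± 12.2 CPM (SD, n = 3) under cool white light, 4.54 ± 3.87 CPM (SD, n = 3) under LEDs and 0.809 ± 0.832 CPM (SD, n = 3) in darkness, against 23.0 ± 4.16 CPM (SD, n = 3) in non-cryopreserved tips. Its mean was 2.58 CPM under LEDs without LED replicate 2 and 0.382 CPM in darkness without dark replicate 2. PGSC0003DMG400027912 was at 5.43 ± 1.25 CPM (SD, n = 3) under cool white light and 0.884 ± 0.610 CPM (SD, n = 3) under LEDs. PGSC0003DMG400023770 was higher under LEDs, at 20.3 ± 6.76 against 5.21 ± 0.758 CPM (SD, n = 3), and stood at 13.9 ± 1.41 CPM (SD, n = 3) in non-cryopreserved tips. PGSC0003DMG400023450 was at 3.81 ± 1.135 CPM (SD, n = 3) under LEDs and 1.16 ± 0.122 CPM (SD, n = 3) under cool white light.

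Many of the genes that were lower under LEDs were also low in darkness, since 160 of the 212 were lower in darkness than under cool white light, where independent lists would share 22.1. Among the 75 genes higher under LEDs, 38 were also higher in darkness than under cool white light, where independent lists would share 3.41. These 2 comparisons share the cool white libraries, and over all genes their fold changes correlated at r = 0.468, against 0.500 for simulated unchanged groups, with a covariance of 0.114 against 0.0367. Relative to non-cryopreserved tips, 120 of the 212 genes were higher and 20 lower under cool white light, where independent lists would give 58.9 and 45.6, and 27 were higher and 97 lower under LEDs, against 57.9 and 49.5. The 212 were chosen for high cool white and low LED values in these same libraries, so these counts are in part a product of that choice.

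In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold changes between LED and cool white light were -3.28 (SE 0.48, adjusted p 0.00776) for PGSC0003DMG400013010, -2.59 (SE 0.46, adjusted p 0.0218) for PGSC0003DMG400027912, 1.96 (SE 0.30, adjusted p 0.0103) for PGSC0003DMG400023770 and 1.69 (SE 0.33, adjusted p 0.0276) for PGSC0003DMG400023450. The log2 fold change of PGSC0003DMG400013010 was -3.95 without LED replicate 2, and that of PGSC0003DMG400027912 was -3.22 without LED replicate 1. LED and cool white libraries did not overlap for 22.4% of tested genes, against an average of 10% by chance, and 3419 genes had an unadjusted p under 0.05. Without the spread of that share between splits, the 22.4% does not decide whether there was an excess. The count of 287 rested on few libraries and on the method. It was 19, 95 and 81 without cool white replicate 2, 1 or 3, 85 without LED replicate 2, 172 without non-cryopreserved replicate 3, 94 when only the 6 libraries compared were fitted, 135 with replicate number as a block, 446 with no filter on low counts and 736 with DESeq2. In the same order, the 75 higher genes became 0, 14, 14, 14, 32, 24, 21, 120 and 314, and the 212 lower genes 19, 81, 67, 71, 140, 70, 114, 326 and 422. The 75 also became 40 without LED replicate 1 and 35 without dark replicate 1. The calls of PGSC0003DMG400013010 and PGSC0003DMG400023770 were lost without cool white replicate 2, where edgeR's adjusted p reached 0.0513 and 0.0756, the highest of their alternatives, which reached down to 0.000433 and 1.96e-07. The calls of PGSC0003DMG400027912 and PGSC0003DMG400023450 were lost in 4 and 7 alternatives, without cool white replicate 1, cool white replicate 2 or LED replicate 2 among them. With DESeq2 size factors the 283 called genes were 103 higher and 180 lower.

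**Figure D4:**
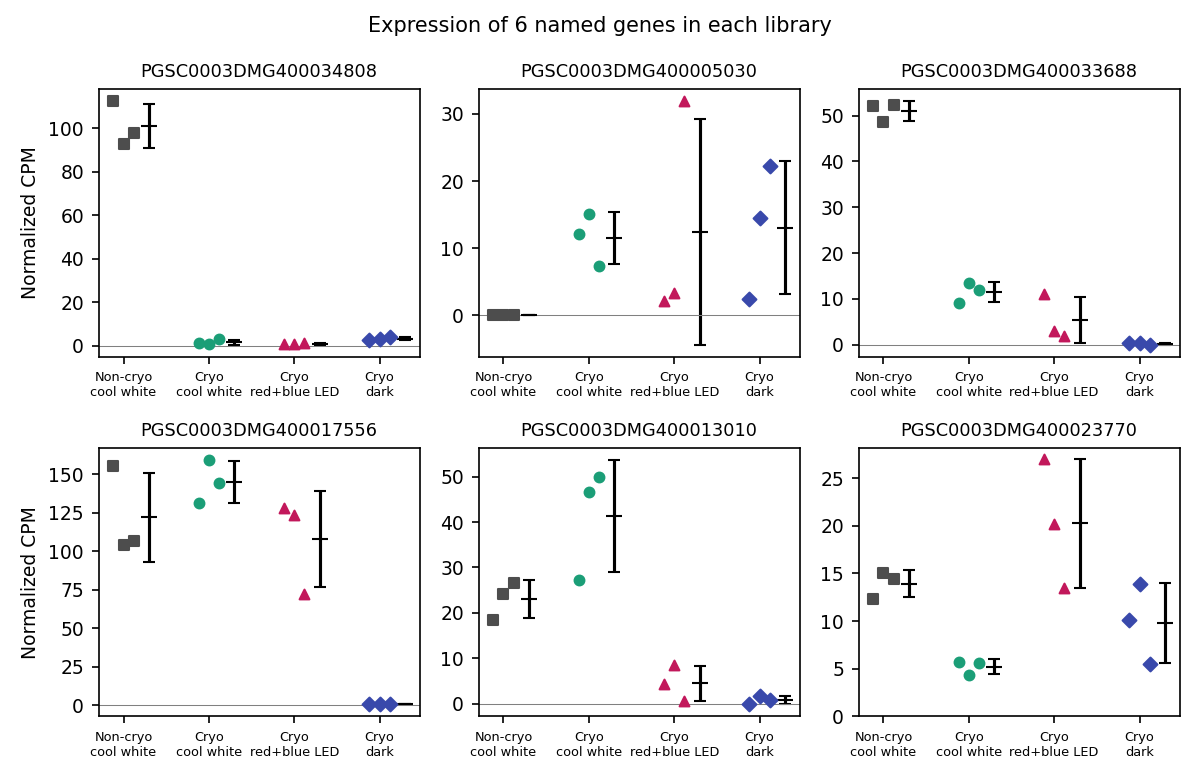
Normalized read counts in CPM (y axis) of 6 genes in each library of the 4 groups (x axis), with a point per library and the mean with a bar of 1 SD (n = 3) beside the points. PGSC0003DMG400034808 is high only in non-cryopreserved tips, PGSC0003DMG400005030 is at 0 only there, and PGSC0003DMG400017556 is near 0 only in darkness.

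A single test of any difference among cool white light, LEDs and darkness called 3122 genes, 15.7% of those tested. This count was 2045 without cool white replicate 2 and 1979 without dark replicate 1.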

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

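The tests weighed for the spread of the LED libraries were chosen only after that spread was seen, except for the test of how widely the shares of non-cryopreserved RNA varied between genes, and the counts of genes with opposite responses were not part of the design fixed beforehand.

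The response to cryopreservation differed in direction between recovery conditions for some genes, each of which also differed in the direct test between those conditions. That test used the same cryopreserved libraries, and opposite calls against shared controls all but fix its outcome, so it adds no support. Between cool white light and darkness there were 140 such genes, of which 133 rose under cool white light and fell in darkness relative to non-cryopreserved tips, and 7 did the opposite. Between LEDs and darkness there were 45, with 42 that rose under LEDs and fell in darkness and 3 that did the opposite. Between LEDs and cool white light there were 11, of which 2 rose under LEDs and fell under cool white light and 9 did the opposite.

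Splits of the 6 libraries of each comparison into 3 and 3 number 10, too few to give a share under 0.05, and in each comparison 1 of the 10, the real split, gave as many genes as observed. For cool white light, LEDs and darkness against non-cryopreserved tips the real splits called 9823, 10086 and 10996 genes and the highest of the other splits 0. The real split called 287 genes and the highest other 2 for LEDs against cool white light, 2986 and 0 for darkness against cool white light, and 2118 and 0 for LEDs against darkness. For any difference among the 9 cryopreserved libraries, 1 of 100 splits drawn, the real split, reached 3122 genes, and the highest other called 1775. That share is under 0.05, which argues against chance as the source of the count. Only 100 of the 280 possible splits were tried, so chance is not excluded.

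The 3 LED libraries lay far apart on the line from non-cryopreserved tips (0%) to tips recovered in darkness (100%), at 58.1% for replicate 1, 75.5% for replicate 2 and 91.0% for replicate 3. This range of 32.9 percentage points compares with 12.1 under cool white light, and it stayed at 32.9 with every library thinned to the smallest total, which argues against depth as its cause, while leaving out the 100 most abundant genes (range 32.9) removed 0.460% of the squared length of the line and so decides nothing. Non-cryopreserved RNA mixed into LED replicate 1 was tested on 73 genes that rose sharply with cryopreservation and 22 genes that fell sharply. The 73 genes would need a median share of 59.8% and the 22 genes 5.61%. The difference was 54.2 percentage points (95% bootstrap interval 44.4 to 63.5). These shares depend on the level taken for unmixed LED tips, and LED replicates 2 and 3 lay apart at 75.5% and 91.0%. The difference therefore does not decide whether there was an admixture. The test written beforehand on the 22 genes left a small admixture open. Their shares varied 1.87 times as widely as in the median resampled mixture but not beyond the widest, 10.2% against 10.3%. Among the 73 genes that rose, whose spread was no part of that test, the shares had an interquartile range of 36.9%. This was beyond the widest of the resampled mixtures (31.6%). Those mixtures put LED replicates 2 and 3 at the same level, although these lay apart on the line, so this spread decides nothing. A dark library mislabelled as LED replicate 3 is argued against by 57 genes at least 16-fold lower in darkness than under cool white light. For these genes LED replicate 3 lay 67.4% of the way toward cool white light (lower quartile 46.7%). No dark library had a median above 0% or an upper quartile above 8.23%. The dark libraries set the 0% point and the choice of genes, so their own medians near 0% follow by construction. The labels name no difference among the LED replicates, so no biological explanation was tested, and differences among the pooled tips or an unrecorded batch could account for the spread.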

How the results depend on the processing

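Thinning and all alternatives for the sets shared between comparisons, other than DESeq2 for the set shared by the 3 cryopreserved groups, were chosen after the data were seen. Counts against non-cryopreserved tips stayed within 1.5 times under every change of scaling, test, filter, samples or depth. They ranged from 9244 to 10044 for cool white light, from 8736 to 10170 for LEDs and from 10536 to 11100 for darkness. A 2-fold minimum, which removes genes by construction, left 3799, 3698 and 4664. For LEDs against cool white light (287 genes), 736 were called with DESeq2, 446 with no filter, 94 when only the groups compared were fitted and 96 at 2-fold. For LEDs against darkness (2118) these 2 last settings gave 1264 and 869, and for darkness against cool white light (2986) they gave 3656 and 1221. The 284 genes lower in both lights became 165 with library size scaling. The cause of these changes was not tested.

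Leaving out each library in turn gave 8297 to 10206 genes for cool white light, 8546 to 10275 for LEDs and 9872 to 11317 for darkness against non-cryopreserved tips. It gave 19 to 328 for LEDs against cool white light, 1991 to 3493 for darkness against cool white light, 1211 to 2997 for LEDs against darkness and 1979 to 4018 for any light difference. The sets higher and lower in all 3 cryopreserved groups ranged from 3314 to 4148 and from 2581 to 3279, and those higher and lower in both lights from 774 to 1383 and from 149 to 375. The 526 alternative values of the 24 named results held 14 calls lost and 0 changes of direction. The naming rule took genes without overlap between groups and with the largest changes, so a change of direction was hardly possible.

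With replicate number as a block, LEDs against cool white light called 135 genes, and every other count stayed within 1.5 times. Numbers shared by replicates showed no pairing. Deviations of same-numbered libraries correlated across genes between -0.24 and 0.20, with 4 of 18 pairs over 0.1, and 4 of 12 libraries correlated best with their own number. Alternatives for the gene lists were not run, since no list had a matched member. At these depths genes near 0.1 CPM have too few reads to be compared.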

Other observations

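The tests on identifiers 1 and 5 numbers apart, and on opposite changes in cool white light against non-cryopreserved tips and LEDs against darkness with and without LED replicate 1, were written before their results were seen. The mirror pair, the counts of calls, the other libraries left out and the identifiers 2 numbers apart were added after.

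Some genes were silent in a whole group while clearly expressed elsewhere. There were 20 genes with no read in the non-cryopreserved libraries and at least 1 CPM in every library of some other group, 3 of them in every library of all other groups. Darkness had 19 such genes, 2 of them at 1 CPM or more in every other library, whereas cool white light and LEDs had 1 each. No gene was read at 1 CPM or more in every library of a single group and absent from all others. Among the 75 genes higher under LEDs than under cool white light, 45 were higher and 5 lower under LEDs than in non-cryopreserved tips, where independent lists would give 20.5 and 17.5, and 19 were higher and 31 lower under cool white light, against 20.8 and 16.1. The 75 were chosen on these same libraries, so the counts are in part a product of that choice, and without cool white replicate 2 the set held 0 genes.

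A hypothesis was that light moves part of the cryopreservation response back toward the level of non-cryopreserved tips. The change from non-cryopreserved tips to cool white light and the difference of LEDs from darkness share no library, and they correlated across genes at r = -0.0411, which does not reach the -0.1 that was set for the hypothesis. The outcome turned on the LED library left out, with r = 0.102 without LED replicate 1 and -0.173 without LED replicate 3. By the rule set beforehand, which named replicate 1 alone, values above -0.1 with and without that library went against the hypothesis. That rule did not foresee the value without LED replicate 3, which lay below -0.1. The cool white response was also measured after light had been given, so genes that light had fully moved back would lie near 0 in it. The 1133 genes higher in both lights than in darkness had a median of 0.05 in that response, against -1.29 in darkness. That set was chosen in part on these libraries. Genes near 0 cannot add to a negative correlation, so an r above -0.1 cannot decide against the hypothesis. The hypothesis therefore stays open, as does the part of LED replicate 1 in it. The mirror pair, LEDs against non-cryopreserved tips and cool white light against darkness, has the same limit. It gave r = -0.106, with values from -0.153 without cool white replicate 1 to -0.0327 without cool white replicate 3. By calls, 244 genes fell under cool white light and were higher under LEDs than in darkness, where independent lists would share 308, and 284 rose under cool white light and were lower under LEDs than in darkness, against 191. Genes that rose in both comparisons numbered 359 against 397, and genes that fell in both 159 against 148. In the mirror pair, 758 genes fell under LEDs and were higher under cool white light than in darkness, against 485, and 330 rose under LEDs and were lower under cool white light than in darkness, against 248. There, 331 genes rose in both comparisons against 567, and 246 fell in both against 212.

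Genes with consecutive identifiers changed together slightly. Over 10121 pairs of tested genes with consecutive numbers, log2 fold changes between cool white and non-cryopreserved tips correlated at a Spearman rho of 0.0873, above the highest of 1000 shuffles (0.0314). Between genes 2 numbers apart rho was 0.0416, still above the highest shuffle (0.0357), and between genes 5 numbers apart it was 0.0133, within the range of the shuffles (highest 0.0296). Related responses of neighbouring genes and reads shared between adjacent similar genes cannot be told apart here, since both predict a correlation limited to close numbers and the positions and sequences of the genes were not used here.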
